A study of Bactrocera dorsalis with 16 samples.

How the data were processed

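Small RNA libraries from ovary and fat body of adult female Bactrocera dorsalis, collected 1, 5, 9 and 13 days after eclosion, were analysed from the single processed table of the series. The 16 libraries form 8 groups of 2 by tissue and day, taken from the sample labels. Per the labels, total RNA was extracted with Trizol, libraries were made with a small RNA kit and sequenced on an Illumina instrument. The authors removed adapter dimers, low complexity sequences, other classes of structural RNA and repeats with the ACGT101-miR software. The aligner, the genome build and the method of scaling are not given in the sources used here. The text of the series speaks of fewer samples than the 16 that the labels list, and the labels were used.

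The deposited table gives normalised values per mature sequence in the unit signal, marked as norm per the file headers, with 2 decimals. Whether these are scaled reads was checked on the values. In each library the low values were multiples of 1 step, between 91.7% and 96.9% of them whole within a tolerance of 0.1, and between 98.4% and 100.0% whole or at a fraction of 1 over 2. Dividing by that step gave recovered reads of 194098 to 1861217 per library, which carry any error of the step and served only the alternatives. No library of a pair was a copy of the other, the chi-square per degree of freedom between replicates lying between 23.49 and 1816.96. The number of reads limits the precision of low values, and reads without molecular identifiers are not independent molecules, so no counting intervals are given. The table had 788 entries for 747 distinct sequences. The 41 repeated entries held identical values and were summed, because low values were not whole in 51.6% of cases for sequences with 2 entries and in 5.9% for those with 1, which marks reads shared out over loci.

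The following was fixed before the data were examined: the groups, the tests, the lists of miRNAs, the rule for named miRNAs and the alternatives, apart from those said below to have been added. Sequences with a value of at least 10 in at least 2 libraries were tested, 321 in all, of which 215 carried a known name and 106 a PC name. Values were taken as log2(value + 1), and limma (version 3.58.1, in R 4.3.3) fitted 8 group means with an intensity trend and no robust setting, on 8 residual and 4.91 prior degrees of freedom. Folds are of value + 1 as fitted. The comparisons were ovary against fat body over the mean of the 4 days and at each day, each step between successive days within a tissue, a joint test over days within each tissue, and the interaction of tissue and day. P-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. The value given for a sequence in a joint test over days is its largest change against day 1 on the log2 scale, in either direction, and its value for the interaction is the largest difference between tissues in the change against day 1.

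Named miRNAs were, for the tissue mean, the 10 called sequences with the largest change in each direction whose highest group mean was at least 100. For the joint tests over days they were the 20 called sequences with the largest range of group means of log2 values, for single days and steps up to 5 in each direction, and for the interaction 10. Members of the lists and the 10 most abundant sequences per tissue could be named as well, and which members of the lists to name was decided after their values were seen. Names are those of the table, in which a prefix such as dvi or ame gives the species of the matching known miRNA and a suffix such as R+1 the bases added or lost at an end.

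The lists were miRNAs of the fly ovary and early embryo, of fat body and metabolism, of mosquito egg development, the let-7 complex, the miR-2, miR-9 and miR-279 families, marker miRNAs of muscle, nerve and gut as other cell types a dissection could hold, the predicted candidates and the conserved sequences. Apart from the last pair of lists they had 126 tested members, of which 26 stood in more than 1 list. The last pair together held all tested sequences, so camera on 1 of them mirrors the other. Lists were tested with camera on log2(value + 1), with the preset correlation of 0.01 and again with an estimated correlation, for the tissue mean and each step within a tissue.

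Replicate numbers were checked as a possible pairing of ovary and fat body. Over 28 pairs of groups the correlation of replicate differences ran from -0.753 (ovary and fat body at day 9) to 0.362, and 9 of 28 lay above 0.1. The numbers were not treated as pairs. A block for replicate number was fitted as an alternative.

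The method was tested on simulated data, in 20 sets of 321 sequences with 90 changed in each. The simulated spread came from the libraries outside day 9. The larger spread between the day 9 replicates is therefore not covered, and recovery in the fit to all 16 libraries may be lower. For the tissue mean it recovered 53.3%, 87.2% and 98.2% of changes of 2-fold, 4-fold and 8-fold, and 3.63% of its calls were unchanged sequences. For a step between days these were 16.2%, 47.3% and 71.3%, with 3.69%.

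Alternatives fixed beforehand were pseudocounts of 0.5 and 10, no filter and a filter of 8 libraries, library totals or RLE size factors as the scale, factors without the 5 most abundant sequences, a robust limma fit, a fit of the compared groups alone, a replicate block, a log2 fold change of at least 1, predicted candidates left out, each entry kept apart, and each library left out in turn. Added after seeing the data were a fit without both day 9 replicate 2 libraries (6 residual and 3.9 prior degrees of freedom, the lone library left being assumed to vary like the other groups), edgeR (4.0.16) and DESeq2 (1.42.0) on recovered reads, TMM factors, and isoforms added together where they shared 15 bases starting within 2 bases of each other. Position and mixing checks and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the fit reported first.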

Results

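Small RNA was sequenced from ovary and fat body of adult female oriental fruit flies, Bactrocera dorsalis, at 1, 5, 9 and 13 days after eclosion, when the adult leaves the pupal case. The ovary makes the eggs, and the fat body is the insect organ for fat storage and yolk protein synthesis. There were 2 libraries for each of the 8 tissue and day groups, 16 in all, and the labels describe each library as a separate sample. The p-values below therefore measure only the spread between these samples. For each sequence that spread is pooled over all 8 groups, so the day 9 libraries enter the p-value of every comparison. The deposited table held 747 distinct mature sequences, of which 373 carried the name of a known miRNA and 374 carried a PC name, the label of the authors' software for a predicted candidate. Values are in the file's normalised signal unit, and their sum per library ranged from 434089 to 1155602 with a median of 689211.0. Read numbers recovered from the spacing of the values ranged from 194098 to 1861217 per library, and between 369 and 520 sequences had a value above 0. The day 5 libraries were the shallowest, at 194098 and 384687 recovered reads in ovary and 213668 and 417165 in fat body. In each tissue the summed signal was lowest at day 5 and highest at day 13. Changes over days are thus not separate from depth and from the method of scaling, which is not given. The candidate pc-3p-116, which the series title names, was in 0 entries of the table under that name and was not analysed here.

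The miRNA miR-276a (bdo-miR-276a) had the highest mean over all days in both tissues. It was the top sequence in 12 of 16 libraries, while miR-8 was in both of fat body day 5, miR-989 in ovary day 9 replicate 1 and miR-994 in the library labelled fat body day 9 replicate 2. It averaged 126642 ± 39952 (SD, n = 8) in ovary, 19.96% of the summed signal, and 241912 ± 97282 (SD, n = 8) in fat body, 29.5%. The miRNA miR-8 (bdo-miR-8_R+1), known in Drosophila to act in the fat body on growth and insulin signalling, followed with 8.62% in ovary and 24.9% in fat body. Its ovary mean of 54670 ± 47109 (SD, n = 8) was raised by the library labelled ovary day 9 replicate 2, described below. In ovary the next were miR-989 (dvi-miR-989-3p_R+1), needed for border cell migration in the Drosophila ovary, with 5.65%, and miR-994 (bdo-miR-994_R+1), abundant in Drosophila ovaries, with 5.14%. These are means over days, and miR-994 stood at 49.8 in ovary at day 1 and at 84811 at day 13. They were followed by miR-31b, miR-184, miR-999, miR-263a, miR-12 and miR-11. In fat body the muscle miRNA miR-1 (bdo-miR-1) took 5.99%, miR-184 4.98% and miR-14, a miRNA of fat metabolism in Drosophila, 2.65%. After these came miR-11, miR-31b, miR-34, miR-263a and miR-994, the last of which stood at 81976 in the library labelled fat body day 9 replicate 2 and at 2140 or less in the other 7 fat body libraries.

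Both libraries labelled day 9 replicate 2 lay apart from the other libraries of their tissue. The library labelled fat body day 9 replicate 2 held 78237 of miR-989 and 26098 of miR-318 (bdo-miR-318), a miRNA abundant in Drosophila ovaries, while its replicate held 1714 and 444. The library labelled ovary day 9 replicate 2 held 166749 of miR-8 and 38734 of miR-1, while its replicate held 64872 and 4400. Across sequences, which are not independent replicates, the library labelled fat body day 9 replicate 2 correlated most with ovary day 9 replicate 1 (r = 0.975, against 0.801 with its own replicate). The library labelled ovary day 9 replicate 2 correlated most with fat body day 9 replicate 1 (r = 0.942, against 0.902 with its own replicate). On 46 sequences that parted the tissues at days 1, 5 and 13, with the mean of fat body set to 0 and that of ovary to 1, the medians of these libraries were 1.20 and 0.41. The other 7 ovary libraries had medians of 0.75 to 1.26, and the other 7 fat body libraries -0.08 to 0.10. Every comparison below uses all 16 libraries as labelled. Counts without both day 9 replicate 2 libraries, a choice made after seeing the data, stand beside the count of called sequences of each comparison. They also stand beside part of the list counts. The fit without both leaves 1 library per tissue at day 9, so its values for a step from or to day 9 are not replicated results.

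**Figure D1:**
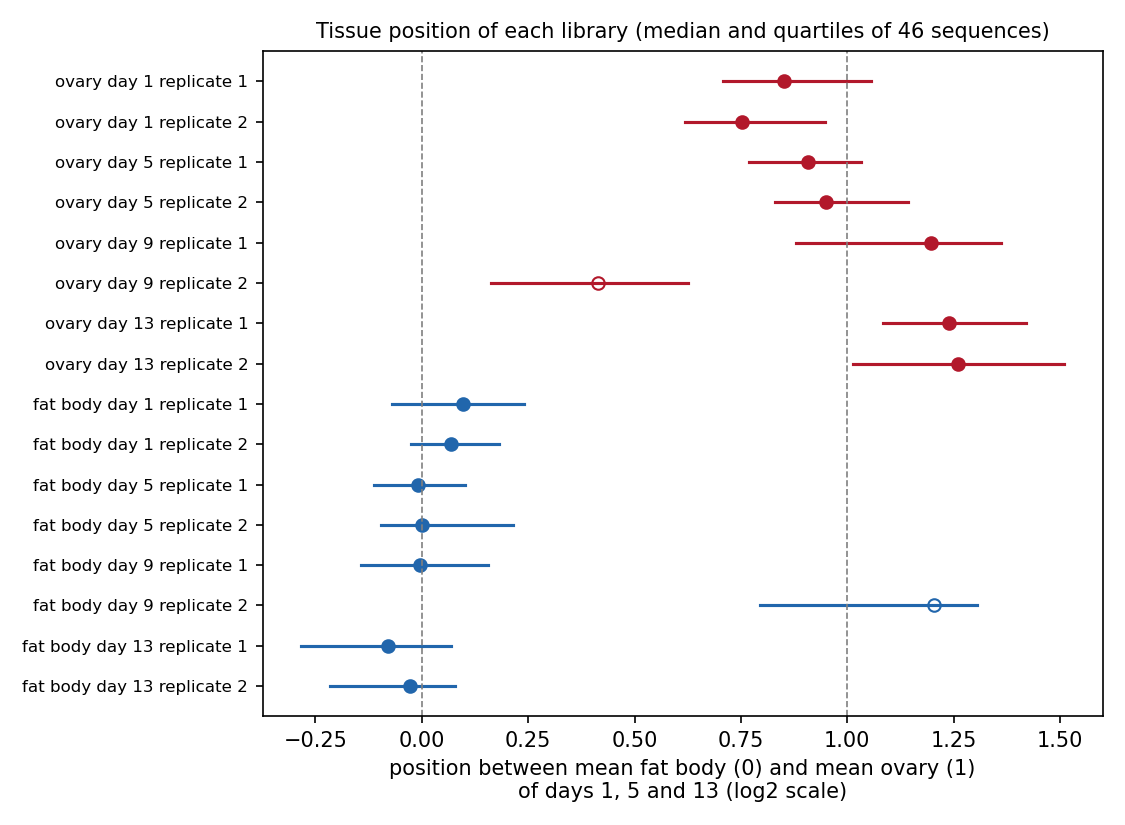
Position of each of the 16 libraries between fat body (0) and ovary (1), as the median (point) and quartiles (bar) over 46 sequences that parted the tissues at days 1, 5 and 13. The library labelled fat body day 9 replicate 2 had a median of 1.20 and the library labelled ovary day 9 replicate 2 a median of 0.41, outside the ranges of -0.08 to 0.10 and 0.75 to 1.26 of the other libraries of their tissues.

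Ovary and fat body were compared over the mean of the 4 days to find the miRNAs that part the organs. The ovary held 20.3-fold more miR-989 (log2 fold change 4.34, SE 0.69, adjusted p = 0.00111, 8 libraries per tissue). It also held more of the miR-92 sequences, by 14.3-fold for miR-92a (ame-miR-92a-3p_L+1, log2 3.84, SE 0.60, adjusted p = 0.00111) and 12.0-fold for miR-92b (bdo-miR-92b, adjusted p = 0.00111). The candidate PC-3p-204_49387 was 15.3-fold higher in ovary (log2 3.93, SE 0.67, adjusted p = 0.00145). Higher in ovary too were PC-3p-13290_1089 (15.2-fold), dme-miR-92b-3p_R+1 (12.4-fold), bdo-miR-11595_R+2 (11.3-fold), dme-miR-995-3p_R+1 (9.58-fold), bdo-miR-286 (7.34-fold) and bdo-mir-5b-1-p5_1ss19GT (7.10-fold). The fat body held 13.2-fold more miR-274 (dme-miR-274-5p_R-1, log2 -3.72, SE 0.48, adjusted p = 0.000536), 4.88-fold more miR-252 (bdo-miR-252, log2 -2.29, SE 0.41, adjusted p = 0.00177) and 4.22-fold more miR-8 (log2 -2.08, SE 0.30, adjusted p = 0.000887). Its star strand dme-miR-8-5p was 3.86-fold higher in fat body. Also higher in fat body were dme-miR-252-5p_R+1 (5.43-fold), bdo-miR-958 (4.69-fold), bdo-miR-981 (4.31-fold), bdo-miR-1 (3.41-fold), dme-miR-1-3p_R+1 (3.21-fold) and isc-miR-1_R+2 (2.97-fold). These folds were larger without both day 9 replicate 2 libraries, at 41.3-fold for miR-989, 27.4-fold for miR-92a, 31.7-fold for PC-3p-204_49387, 22.4-fold for miR-274 and 7.64-fold for miR-252. In all, limma called 119 of 321 sequences at an adjusted p under 0.05, 79 higher and 40 lower in ovary, and 25 of them were predicted candidates. It called 174 (111 higher, 63 lower) without both day 9 replicate 2 libraries, 117 of them shared. With library totals as the scale, the split was 104 higher and 19 lower, with the median of all sequences moved by 0.353 on the log2 scale, and without ovary day 9 replicate 1 the count was 78.

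Members of the miRNA lists fixed beforehand are sequences, so isoforms and both arms of 1 miRNA count separately and are not independent. Sequences of the fly ovary and early embryo list were mostly higher in ovary. Of 39 tested members, 31 were higher and 1, miR-184, was lower; adjusted over the list alone, 32 were higher and 3 lower, and camera gave an adjusted p of 1.5e-06 (adjusted p = 0.522 with an estimated correlation). Of these members 34 were higher and 4 lower without both day 9 replicate 2 libraries. Members higher in ovary included miR-7 (bdo-miR-7_R-3, log2 2.21, adjusted p = 0.00118) and miR-318 (log2 2.21, SE 0.75, adjusted p = 0.0348). The fat body and metabolism list lay the other way, with 10 of 22 members lower in ovary and 0 higher, and 10 lower adjusted over the list alone. Besides miR-8, these included miR-277 (dme-miR-277-3p, known in Drosophila to act on branched-chain amino acid catabolism, 2.85-fold, SE 0.33 on the log2 scale, adjusted p = 0.00612), miR-278 (dme-miR-278-3p, a miRNA of energy balance, 2.44-fold, adjusted p = 0.0161) and miR-276a (1.82-fold, adjusted p = 0.0243). The camera result was an adjusted p of 9.65e-08 (adjusted p = 0.522 with an estimated correlation; without both day 9 replicate 2 libraries these were 6.03e-09 and 0.0407, and 15 members were lower).

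Markers of other cell types also differed. In the muscle list, 3 of 4 miR-1 sequences were lower in ovary, and 3 adjusted over the list alone. The camera adjusted p was 0.021 (adjusted p = 0.522 with an estimated correlation). Of the let-7 complex, miRNAs made from 1 transcript, miR-100 (bdo-miR-100, log2 -1.11, adjusted p = 0.00612) and let-7 (bdo-let-7, log2 -0.71, adjusted p = 0.0334) were lower among 11 members. Adjusted over the list alone 1 was lower, and the camera adjusted p was 0.0292 (adjusted p = 0.522 with an estimated correlation), while the list's median of -0.24 turned to 0.14 with library totals as the scale. Among neural miRNAs, miR-1000 (log2 -1.74, adjusted p = 0.0101) and miR-137 (log2 -1.14, adjusted p = 0.0377) were lower in ovary, 2 of 7 over all sequences and 2 adjusted over the list alone (camera adjusted p = 0.117). The list's median of -0.35 was 0.02 with library totals. Of the gut list 3 of 9 members were lower in ovary, and 3 adjusted over the list alone (camera adjusted p = 0.117). In the fit without both day 9 replicate 2 libraries the members lower in ovary were 4 of the muscle list, 3 of the let-7 complex, 3 of the neural list and 4 of the gut list. In the gut list 2 were then higher. With all libraries, members that did not pass included miR-125 (bdo-miR-125, log2 -0.24, adjusted p = 0.343) of the let-7 complex, miR-124 (bdo-miR-124, log2 -0.35, adjusted p = 0.559) of the neural list and miR-263a (bdo-miR-263a_R-3, log2 0.09, adjusted p = 0.821) of the gut list. The sign of each of these turned under at least 1 other scaling, and without both day 9 replicate 2 libraries miR-263a was called higher in ovary (log2 0.51, adjusted p = 0.00195).

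For the remaining lists the camera test did not pass with all libraries. In the miR-2 family 7 of 24 members were higher and 1 lower, in the miR-9 family 5 of 12 were higher and 0 lower, and in the miR-279 family 3 of 6 were higher and 0 lower. Adjusted over the list alone these counts were unchanged, and the camera adjusted p was 0.0561, 0.193 and 0.219. The 3 members of the miR-279 family that were higher were its miR-286 sequences. These belong to the miR-309 cluster and are also counted in the ovary and early embryo list. The mosquito egg development list had 5 of 18 members higher and 5 lower, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.193). Its median was -0.13, its mean 0.24 and its test pointed down, and with library totals the median was 0.24. Its member miR-275 (bdo-miR-275) stood near 0 (log2 -0.01, adjusted p = 0.976), with a sign that turned with library totals. Of 106 predicted candidates 21 were higher and 4 lower, with 19 and 3 adjusted over the list alone. Of 215 conserved sequences 58 were higher and 36 lower, with 63 and 39 adjusted over the list alone, and camera gave an adjusted p of 0.394 for both lists. The conserved sequences had a median of 0.13 and a mean of 0.31, and their test pointed down. In the fit without both day 9 replicate 2 libraries the members higher and lower were 15 and 1 of the miR-2 family (camera adjusted p = 0.0275, and adjusted p = 0.16 with an estimated correlation), 8 and 0 of the miR-9 family, 3 and 0 of the miR-279 family, 6 and 5 of the mosquito list, 28 and 14 of the candidates and 83 and 49 of the conserved sequences.

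The tissues were also compared at each day, with 2 libraries per group. At day 1 the ovary held 28.5-fold more miR-92a (log2 4.83, adjusted p = 0.0443), 27.7-fold more miR-92b and 6.08-fold more miR-317 (dme-miR-317-3p_R-2_2ss21CT22AC, log2 2.60, adjusted p = 0.00215). The fat body held 7.02-fold more dme-miR-8-5p (adjusted p = 0.00933) and 5.41-fold more miR-8. At day 5 miR-7 was 9.40-fold higher in ovary (adjusted p = 0.0381) and miR-8 6.70-fold higher in fat body (adjusted p = 0.0377). At both days dme-miR-999-3p_R+1 (5.52-fold and 5.14-fold) and miR-316 (bdo-miR-316, 3.97-fold and 3.15-fold) were higher in ovary, and at day 5 also bdo-miR-999 (3.81-fold), while dme-miR-8-5p was 4.82-fold higher in fat body. The day 1 count was 10 (8 higher and 2 lower in ovary) and the day 5 count 7 (5 higher, 2 lower), against 58 (39 higher, 19 lower) and 88 (54 higher, 34 lower) without both day 9 replicate 2 libraries. Neither comparison holds a day 9 library, and the fold changes were the same in both fits (log2 4.83 for miR-92a at day 1). Only the pooled spread and its degrees of freedom differed, so the lower counts do not show that few sequences differed at these days. Other scalings split the counts at day 1 as 9 and 1 (library totals), 11 and 1 (TMM) or 1 and 1 (TMM without the 5 most abundant sequences). At day 5 the splits were 35 and 6 (library totals) or 18 and 4 (TMM). At day 1 the count was 0 without replicate 1 of ovary or fat body at day 1, 1 without replicate 2 of either, 3 without any library of day 5 or of fat body day 13, and 6 without either of ovary day 13. It was 29 or 28 without fat body day 9 replicate 1 or 2. At day 5 it was 0 without any single library of day 1 or 13, of ovary day 5 or replicate 1 of fat body day 5, and 1 without replicate 2 of the latter. It was 32 or 30 without ovary day 9 replicate 1 or 2, and 58 or 60 without fat body day 9 replicate 1 or 2.

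At day 13 the tissues lay farthest apart in the number of called sequences. The ovary held 447-fold more miR-318 (log2 8.81, SE 1.49, adjusted p = 0.00122), at 37822 ± 6104 (SD, n = 2) against 149 ± 176 in fat body. Members of the miR-309 cluster, which in Drosophila embryos takes part in clearing maternal mRNA, were higher, as folds of value + 1, by 418-fold (bdo-mir-4-p5), 416-fold (bdo-miR-286), 375-fold (bdo-mir-5a-p3) and 369-fold (dme-miR-5-3p). The fat body held 180-fold more miR-274 (log2 -7.49, SE 0.96, adjusted p = 0.000618), 77.8-fold more miR-252 and more miR-1 (log2 -4.36, adjusted p = 0.00296), with dme-miR-252-5p_R+1 at 77.5-fold and dme-miR-1-3p_R+1 at 18.5-fold. In fat body miR-1 stood at 80855 ± 2573 and in ovary at 3961 ± 658 (SD, n = 2). In all, 144 sequences were called (98 higher and 46 lower in ovary), and 177 (114 higher, 63 lower) without both day 9 replicate 2 libraries, 143 of them shared. The split was 79 and 74 with TMM and 76 and 69 with TMM without the 5 most abundant, which moved the median of all sequences by -0.484 and -0.433. The count was 80 without fat body day 13 replicate 2, 83 without its replicate 1 and 89 without ovary day 13 replicate 1.

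At day 9 the libraries of each tissue differed from each other by more than the tissues did. The miR-989 values were 81674 and 12696 in the libraries labelled ovary and 1714 and 78237 in those labelled fat body, and the miR-8 values were 64872, 166749, 284047 and 65452 in the same order. Limma called 0 sequences (1 at an unadjusted p under 0.05), and edgeR and DESeq2 on the recovered reads called 0 each. Leaving out both day 9 replicate 2 libraries leaves 1 library per tissue at day 9. The spread is then borrowed from the other groups, so the count that follows is not a replicated result. Without both day 9 replicate 2 libraries limma called 111 (80 higher and 31 lower in ovary), and without fat body day 9 replicate 2 alone 30.

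Over days 1 to 13 miR-318, miR-994, miR-989 and the sequences of the miR-309 cluster named here rose in ovary. The level of miR-318 was 18.4 ± 4.45 at day 1, 42.2 ± 7.55 at day 5 and 37822 ± 6104 at day 13 (SD, n = 2), a change against day 1 of up to 1960-fold (log2 10.94, adjusted p = 3e-04). The level of miR-6 (bdo-miR-6) was 16.5 ± 3.12, 50.3 ± 13.5 and 47478 ± 15707 on the same days, up to 2660-fold (log2 11.38), and that of miR-994 went from 49.8 ± 1.31 to 84811 ± 23094, up to 1640-fold (log2 10.68). For miR-989 the largest change was 5.73 on the log2 scale (adjusted p = 0.0277). The largest changes against day 1 were 3140-fold for bdo-mir-4-p5, 3020-fold for dme-miR-6-3p_R-2_1ss1TC, 2080-fold for bdo-miR-309b, 1360-fold for bdo-miR-286, 1310-fold for bdo-miR-4_R-2, 1150-fold for bdo-miR-309a_R-2 and 1050-fold for bdo-miR-5b. All 20 sequences that the naming rule took here had their lowest mean before day 9. Folds are of value + 1, so for sequences near 0, such as bdo-mir-4-p5 with 0.36 at day 1, their size depends on the pseudocount. The joint test over days called 87 sequences, 28 of the 39 of the ovary and early embryo list among them (29 adjusted over the list alone). Of the fat body and metabolism list it called 5 of 22 (5 adjusted over the list alone). It called 176 without both day 9 replicate 2 libraries, of which 85 were shared. The count was 56 without ovary day 13 replicate 1, and 154 or 150 without fat body day 9 replicate 1 or 2.

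**Figure D2:**
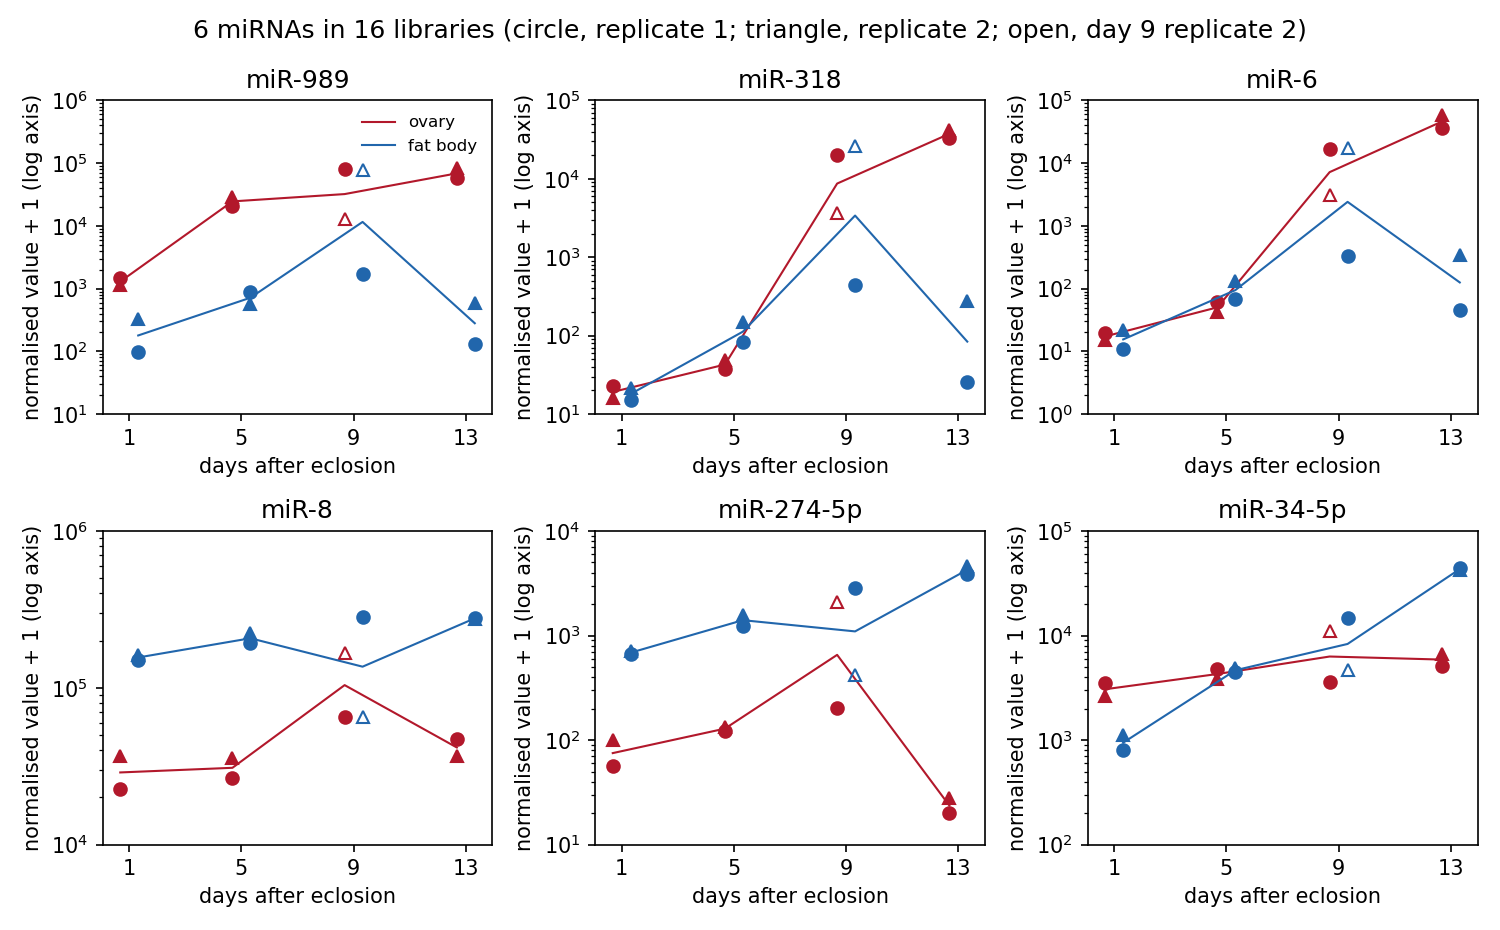
Value + 1 of 6 miRNAs (log axis, normalised signal) against days after eclosion in ovary (red) and fat body (blue); circles are replicate 1, triangles replicate 2, open symbols the libraries labelled day 9 replicate 2, and lines join the group means of log2 values. Ovary miR-318 stood at 18.4 at day 1 and 37822 at day 13, while fat body miR-34-5p stood at 957 and 43258.

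Between days 1 and 5 the ovary's miR-989 value went from 1305 ± 226 to 24895 ± 5272 (SD, n = 2), a 19.0-fold difference that did not pass the test (log2 4.25, SE 1.38, adjusted p = 0.215; 0.0123 without both day 9 replicate 2 libraries). Limma called 0 sequences at this step (48 at an unadjusted p under 0.05), edgeR 0 and DESeq2 7. The step holds no day 9 library, but its p-values use the spread pooled over all groups, those of day 9 included. Without both day 9 replicate 2 libraries limma called 32 (18 higher and 14 lower at day 5), among them miR-31b (dme-miR-31b-5p_R+1_1ss15AC), which went from 62339 ± 1181 to 25905 ± 5189 (adjusted p = 0.19 with all libraries, 0.00746 without). The count was 1 without ovary day 5 replicate 1, 2 without either library of fat body day 5 and 4 without either of fat body day 9. None of the 12 lists passed camera with all libraries, the lowest adjusted p being 0.0686. Without both day 9 replicate 2 libraries the mosquito egg development list passed upward, with 4 of 18 members higher and 5 adjusted over the list alone (adjusted p = 0.0288, and adjusted p = 0.698 with an estimated correlation).

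Between days 5 and 9, 20 of the 39 sequences of the ovary and early embryo list, isoforms counted separately, rose in ovary. The largest rises were in miR-5b (216-fold, log2 7.75, SE 1.49, adjusted p = 0.0111), miR-318 (204-fold, log2 7.67, adjusted p = 0.0111), miR-994 (189-fold), miR-6 (143-fold) and bdo-mir-5a-p3 (130-fold). The sequences that fell were miR-316 (3.05-fold, log2 -1.61, adjusted p = 0.0172), bdo-miR-999 (2.98-fold, adjusted p = 0.0273) and miR-31b (2.91-fold, log2 -1.54, adjusted p = 0.0134). The fit without both day 9 replicate 2 libraries leaves 1 ovary library at day 9, so its values for this step are not replicated. In that fit the rise was 480-fold for miR-5b, 477-fold for miR-318 and 434-fold for miR-994. The count was 26 (23 rose, 3 fell), and 77 (60 and 17) without both day 9 replicate 2 libraries, with all 26 shared. It was 0 without ovary day 5 replicate 1, ovary day 5 replicate 2 or ovary day 9 replicate 1, and the split was 22 and 14 with library totals and 30 and 0 with TMM without the 5 most abundant. Adjusted over the list alone, 24 sequences of the ovary and early embryo list rose (camera adjusted p = 3.69e-12, and adjusted p = 0.227 with an estimated correlation). Members that did not pass in either fit included bdo-miR-7_R-3 (log2 -1.55, and -0.57 without both libraries), bdo-miR-184 (-0.07 and -0.29) and bdo-miR-92b, whose sign turned (-0.27 and 0.91).

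Other lists passed camera at this step in ovary. They are not all separate from the ovary and early embryo list. The 2 members of the miR-279 family called by limma with all libraries were miR-286 sequences, which stand in both lists. The muscle list and the miR-279 family passed in the fit without both day 9 replicate 2 libraries and not with all libraries. The miR-279 family had 4 of 6 members that rose and 4 adjusted over the list alone (adjusted p = 0.0307, and adjusted p = 0.122 with an estimated correlation), against 2 and 3 with all libraries (camera adjusted p = 0.0543). The muscle list had 3 of 4 miR-1 sequences lower at day 9 (4 adjusted over the list alone; median -2.09, adjusted p = 0.000323, and adjusted p = 0.0484 with an estimated correlation). With all libraries 0 of 4 were called by limma or adjusted over the list alone (camera adjusted p = 0.205 for the muscle list). The mosquito egg development list had 3 of 18 members that rose (5 adjusted over the list alone), with a median of 1.51 and a camera adjusted p of 0.00101 (adjusted p = 0.0941 with an estimated correlation). The miR-9 family, which holds miR-4 sequences of the miR-309 cluster, had 2 of 12 that rose (3 adjusted over the list alone; camera adjusted p = 0.0217, and adjusted p = 0.555 with an estimated correlation; without both day 9 replicate 2 libraries 5 rose, and these were 0.0024 and 0.0484). The gut list had 0 of 9 called by limma or adjusted over the list alone, with a median of 1.40 and a camera adjusted p of 0.0217 (adjusted p = 0.115 with an estimated correlation, and 0.159 with the preset correlation without both day 9 replicate 2 libraries). Conserved sequences were placed higher (23 rose and 3 fell, and 27 and 4 adjusted over the list alone) and the 106 predicted candidates lower (0 called either way), each with a camera adjusted p of 0.00101 (adjusted p = 0.0941 and adjusted p = 0.269 with an estimated correlation). Camera compares each of these lists with the other, so the opposite directions are 1 result and not 2. The candidates' median of -0.34 was -0.08 without both day 9 replicate 2 libraries, where 7 rose and 3 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0301, and adjusted p = 0.412 with an estimated correlation).

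Between days 9 and 13 the ovary lost miR-274, from values of 202 and 2105 in the day 9 libraries to 23.0 ± 5.81 (SD, n = 2) at day 13 (27.6-fold, log2 -4.79, adjusted p = 0.041). The fall was 8.56-fold (log2 -3.10) without both day 9 replicate 2 libraries, where 1 ovary library is left at day 9. The miR-309 cluster member dme-miR-4-3p, below the abundance the naming rule asked for and chosen after its values were seen, rose (log2 5.22, adjusted p = 0.0129) to 65.8 at day 13. These were the 2 called sequences, against 5 (4 rose, 1 fell) without both day 9 replicate 2 libraries, and 1 higher and 2 lower with library totals or with TMM and 1 and 3 with TMM without the 5 most abundant. The count was 0 without ovary day 9 replicate 2 or ovary day 13 replicate 1, 21 without ovary day 9 replicate 1, 30 or 27 without fat body day 9 replicate 1 or 2, and 1 without any other single library. The ovary and early embryo list passed camera upward at this step, with a median of 2.01 and 1 member that rose (3 adjusted over the list alone; adjusted p = 0.00477). The miR-2 family (median 0.86, 0 called, 2 higher adjusted over the list alone, adjusted p = 0.0274) and the miR-9 family (median 1.52, 1 rose, 1 adjusted over the list alone, adjusted p = 0.0312) passed upward too. The fat body and metabolism list (median -0.25, adjusted p = 0.0203), the let-7 complex (median -0.41, adjusted p = 0.00975) and the muscle list (median -1.79, adjusted p = 0.0274) passed downward with 0 members called by limma or adjusted over the list alone. Without both day 9 replicate 2 libraries the medians of the upward lists were 0.71 (ovary and early embryo), 0.36 (miR-2 family) and 0.74 (miR-9 family). Those of the downward lists were 0.30 (fat body and metabolism, a turned sign), -0.32 (let-7 complex) and -0.24 (muscle). Each of the 6 camera calls was lost with an estimated correlation (adjusted p = 0.548 with an estimated correlation for all 6). With the preset correlation and without both day 9 replicate 2 libraries 4 were lost: the fat body and metabolism list (0.755), the miR-2 family (0.0801), the miR-9 family (0.159) and the muscle list (0.205).

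In fat body the clearest changes over days were in miR-34 and miR-317. The level of miR-34 (dvi-miR-34-5p), a miRNA tied to ageing in Drosophila, was 957 ± 231 at day 1, 4658 ± 274.7 at day 5 and 43258 ± 1363 at day 13 (SD, n = 2), a change against day 1 of up to 45.8-fold (log2 5.52, adjusted p = 0.000483). The level of miR-317 was 780 ± 145, 3194 ± 441 and 27513 ± 36 on the same days, up to 35.5-fold (log2 5.15, adjusted p = 6.52e-06). The candidate PC-3p-36663_319 had a largest change of 16.2-fold (adjusted p = 0.0313), and miR-87a (api-miR-87a), at 7.98 at day 1, 47.6 at day 5 and listed at 0 at day 13, was called with a largest change against day 1 of -3.05 on the log2 scale (adjusted p = 0.0313), whose direction turned with a pseudocount of 10. Also called were miR-252 (log2 2.81, adjusted p = 0.0409) and miR-14 (log2 1.74, adjusted p = 0.0105), which reached 7777 ± 134 and 47989 ± 6656 at day 13. The joint test called 53 sequences, and 98 without both day 9 replicate 2 libraries, 46 of them shared.

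The largest changes of late ovary miRNAs in fat body were set mostly by the library labelled fat body day 9 replicate 2. They were 222-fold for miR-994 (log2 7.79, adjusted p = 0.0232), 218-fold for miR-5b, 189-fold for miR-318 and 64.6-fold for miR-989, and without both day 9 replicate 2 libraries those of miR-994 and miR-318 were 5.17 and 4.62 on the log2 scale. In that fit the call was lost for bdo-mir-4-p5 (adjusted p = 0.114), bdo-miR-4_R-2 (0.0605), bdo-miR-309a_R-2 (0.0607), dme-miR-5-3p (0.112), dme-miR-994-3p_L+1R-1 (0.0708) and aae-miR-286a_R-1_4ss20CT22TC23CT24CA (0.053). The rule also took bdo-miR-6 (156-fold), bdo-miR-286 (142-fold), bdo-miR-5a (log2 7.06), bdo-mir-4-p5 (103-fold) and 8 others of the ovary list between 30.2-fold and 127-fold. Of the ovary and early embryo list 16 of 39 were called over days in fat body (21 adjusted over the list alone), and of the fat body and metabolism list 3 of 22 (4 adjusted over the list alone). These became 12 (18) and 11 (13) without both day 9 replicate 2 libraries. Without 1 library the count was 4 or 11 (fat body day 1 replicate 2 or 1), 12 or 14 (fat body day 13 replicate 1 or 2), 16 or 17 (fat body day 5 replicate 1 or 2), 34 (either of ovary day 5) and 160 (fat body day 9 replicate 1).

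Between days 1 and 5 the fat body gained miR-317 (4.11-fold, log2 2.04, SE 0.36, adjusted p = 0.0191), miR-275 (bdo-miR-275, a miRNA needed for egg development in mosquitoes, 3.82-fold, SE 0.36, adjusted p = 0.0191) and the candidate PC-3p-184721_37 (listed at 0 at day 1 and at 36.1 at day 5, adjusted p = 0.0331), which was chosen after its values were seen. The level of miR-275 was 2180 ± 42 at day 1 and 8346 ± 962 at day 5 (SD, n = 2). These 3 sequences were all that was called, against 32 (21 higher, 11 lower) without both day 9 replicate 2 libraries. The count was 0 without either library of fat body day 1 or 13 or replicate 1 of fat body day 5, 5 without any of ovary day 9 or 13, and 10 or 12 without fat body day 9 replicate 1 or 2. It was 0 with TMM. The mosquito egg development list passed camera with 1 of 18 members called (2 adjusted over the list alone; median 0.72, adjusted p = 0.0403, and adjusted p = 0.483 with an estimated correlation). In the fit without both day 9 replicate 2 libraries 3 were called (7 adjusted over the list alone), and the ovary and early embryo list passed upward too with 2 of 39 called (0 adjusted over the list alone). The adjusted p was then 0.0127 for each list (adjusted p = 0.76 with an estimated correlation).

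Between days 5 and 9 limma called 0 sequences in fat body (78 at an unadjusted p under 0.05), edgeR 23 and DESeq2 44. The fit without both day 9 replicate 2 libraries leaves 1 fat body library at day 9, so its values here are not replicated. Without both day 9 replicate 2 libraries miR-34 (log2 1.65, adjusted p = 0.0301) and miR-317 (log2 1.85, adjusted p = 0.00466) were the 2 called, and without fat body day 9 replicate 1 alone the count was 117. The ovary and early embryo list passed camera upward (0 of 39 called, 23 adjusted over the list alone; median 3.71, adjusted p = 3.71e-08, and adjusted p = 0.768 with an estimated correlation); without both day 9 replicate 2 libraries its median was 1.02. The miR-279 family passed upward with 0 of 6 called and 4 adjusted over the list alone, and the let-7 complex downward with 0 of 11 called either way (camera adjusted p = 0.0419 for both, and adjusted p = 0.768 with an estimated correlation). Their adjusted p was 0.306 and 0.655 without both day 9 replicate 2 libraries.

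Between days 9 and 13 miR-14 rose in fat body from 13618 ± 685 to 47989 ± 6656 (SD, n = 2; 3.51-fold, log2 1.81, adjusted p = 0.039). It was the 1 called sequence, and without both day 9 replicate 2 libraries 11 were called (8 higher, 3 lower), among them miR-252 (log2 1.98) and miR-34 (log2 1.57), each at an adjusted p of 0.0177. The count was 8 or 9 without ovary day 9 replicate 2 or 1, 101 without fat body day 9 replicate 1, and 0 without any other single library; with TMM the split was 2 higher and 3 lower. The fat body and metabolism list passed camera upward (1 of 22 rose, 2 adjusted over the list alone; median 1.13, adjusted p = 9.32e-06), and the ovary and early embryo list downward (0 of 39 called, 19 lower and 1 higher adjusted over the list alone; median -3.38, adjusted p = 4.31e-09). The estimated correlation ended both calls (adjusted p = 0.483 with an estimated correlation for each). Values for this step without both day 9 replicate 2 libraries rest on 1 fat body library at day 9. The miR-9 family passed downward (0 of 12 called, 4 adjusted over the list alone; adjusted p = 0.00336, and adjusted p = 0.619 with an estimated correlation). Without these 2 libraries of day 9 the ovary and early embryo list had a median of -0.82, with 1 member lower and 0 adjusted over the list alone (adjusted p = 0.00183, and adjusted p = 0.463 with an estimated correlation). In that fit the adjusted p of the fat body and metabolism list and the miR-9 family was 0.0787, and the gut list passed downward with 0 of 9 called by limma or adjusted over the list alone (adjusted p = 0.0279, and adjusted p = 0.463 with an estimated correlation).

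Whether the course over days differed between the tissues was tested with the interaction of tissue and day. The late ovary miRNAs differed most, their change against day 1 being larger in ovary than in fat body by 9.62 on the log2 scale for bdo-mir-4-p5, 8.72 for miR-318 and 8.70 for bdo-mir-5a-p3. The other named sequences were bdo-miR-309b (8.57), miR-994 (8.53), miR-6 (8.36), bdo-miR-4_R-2 (7.92), bdo-miR-309a_R-2 (7.91), dme-miR-6-3p_R-2_1ss1TC (7.44) and miR-5b (7.31), and their adjusted p was 0.0404 except for bdo-miR-4_R-2 (0.0441). In the other direction, and chosen after their values were seen, miR-34 (log2 -4.58, adjusted p = 0.0404) and miR-317 (log2 -4.28, adjusted p = 0.00327) gained more in fat body. The interaction called 36 sequences. It called 19 of the 39 sequences of the ovary and early embryo list (26 adjusted over the list alone). It called 1 of 22 of the fat body and metabolism list (1 adjusted over the list alone). It called 97 without both day 9 replicate 2 libraries, with all 36 shared, and these lists then had 31 of 39 (34 adjusted over the list alone) and 10 of 22 (11). The count was 1 without any single library of days 1, 5 or 13. It was 56 without ovary day 9 replicate 1, 108 or 61 without fat body day 9 replicate 1 or 2, and 4 with library totals. On the recovered reads edgeR called 0 and DESeq2 50, and limma with a block for replicate number called 1.

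Members of the remaining lists were counted in the same tests. In ovary the joint test called 10 of 18 sequences of the mosquito egg development list (13 adjusted over the list alone), 7 of 12 of the miR-9 family (9), 6 of 24 of the miR-2 family (7), 5 of 9 of the gut list (7), 4 of 6 of the miR-279 family (4) and 1 of 11 of the let-7 complex (0). In fat body these counts were 4 (8), 3 (4), 3 (3), 0 (0), 2 (2) and 1 (1). For the interaction they were 2 (3), 6 (10), 4 (5), 4 (5), 1 (3) and 0 (0), with the counts adjusted over the list alone in brackets. Of the muscle and neural lists 0 of 4 and 0 of 7 members were called by limma in any of these tests with all libraries, and 0 adjusted over the list alone. Without both day 9 replicate 2 libraries 3 of 4 muscle sequences were called in ovary, 1 in fat body and 3 for the interaction (4, 2 and 4 adjusted over the list alone), and 2, 0 and 0 of 7 neural ones (1, 0 and 0 adjusted over the list alone). In that fit 5 of 11 of the let-7 complex were called in ovary (2 adjusted over the list alone), 34 of 39 of the ovary and early embryo list and 12 of 22 of the fat body and metabolism list. Of the predicted candidates 18 of 106 were called in ovary (5 adjusted over the list alone), 17 in fat body (17) and 3 for the interaction (0). Of the conserved sequences the counts were 69 of 215 (74), 36 (37) and 33 (41). The median, mean and test of a list differed in sign at single steps. In ovary they did so for the fat body and metabolism list and the let-7 complex between days 1 and 5, for the let-7 complex, miR-2 family and neural list between days 5 and 9, and for the gut list and conserved sequences between days 9 and 13. In fat body they differed for the miR-279 and miR-9 families and conserved sequences between days 1 and 5, for the gut list and predicted candidates between days 5 and 9, and for the mosquito egg development list and predicted candidates between days 9 and 13.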

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

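The test for a difference between the tissues in their course over days was planned, while the position, mixing, carry-over and split tests below were chosen only after the results were seen.

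The interaction of tissue and day called 36 sequences, each marked here because the effect of day differed between ovary and fat body. For the 10 named ones the change against day 1 was larger in ovary than in fat body, by 7.31 for bdo-miR-5b, 8.72 for bdo-miR-318, 8.70 for bdo-mir-5a-p3, 9.62 for bdo-mir-4-p5, 8.36 for bdo-miR-6, 8.53 for bdo-miR-994_R+1, 8.57 for bdo-miR-309b, 7.92 for bdo-miR-4_R-2, 7.91 for bdo-miR-309a_R-2 and 7.44 for dme-miR-6-3p_R-2_1ss1TC on the log2 scale. The count was 97 without both day 9 replicate 2 libraries, but 1 without any single library of days 1, 5 or 13, 4 with library totals, 1 with a replicate block and 0 with edgeR on recovered reads. With 2 libraries per group, no library could be tested as an outlier within its group.

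Both libraries labelled day 9 replicate 2 lay toward the other tissue. On 64 sequences that already parted the tissues at days 1 and 5, the median of the library labelled ovary day 9 replicate 2 was 0.393. That lay below the ovary mean at 1, near which an ovary that only matured late would lie. The 95% bootstrap interval was 0.152 to 0.581, and the upper quartile over sequences was 0.753. The interval replaced the upper quartile as the deciding value after both were seen. Since the values also come from 1 library, a late ovary is not decided by them. Exchanged labels may account for the pattern. The library labelled fat body day 9 replicate 2 had a median position of 1.20 and its partner one of 0.413, both out of place. These positions are what raised the question, so they are not a separate test of an exchange. An exchange alone would put the partner near 0, and ovary RNA mixed into it may be added. Its median ovary share was 18.1% over 14 sequences higher in ovary (bootstrap interval 15.3 to 21.02). Over 11 sequences higher in fat body it was 19.1% (3.7 to 32.0). A library between the tissues gives such a share whatever the reason, so the shares do not test mixing. These bootstrap intervals resample sequences of 1 library, which are not independent. They therefore measure a spread over sequences and not the spread between ovaries. Exchange, mixing at dissection or later, and an ovary that matured late all stay open, and a difference between single flies was not tested.

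Late ovary miRNAs were present at a low level in the fat body libraries other than the one labelled day 9 replicate 2. They were taken here as 15 sequences of miR-994, miR-318 and the miR-309 cluster at 500 or more in ovary day 9 replicate 1. Other members of the ovary list, such as miR-989, were not in this set. At day 1 the late sequences stood at medians of 53.4% and 81.3% of ovary day 1 in fat body replicates 1 and 2 (13 and 14 sequences above 0). The source of their low values in ovary at days 1 and 5 was not tested, and the ovary folds over days rest on those values. At day 5 ovary RNA of the same day is argued against, since the late sequences stood at medians of 87.3% and 173.8% of ovary day 5 in replicates 1 and 2, and at 24.0% and 58.3% or more, while 10 and 18 of 38 other sequences above 1000 in ovary day 5 lay below those minima, down to 2.42% and 1.57% for miR-989. Reads or RNA of a later ovary may be the source there, with an SD of the log2 ratio of 0.478 to ovary day 13 in replicate 1 (0.914 to ovary day 9 replicate 1) and of 0.413 to ovary day 9 replicate 1 in replicate 2 (0.892 to ovary day 13), so that the nearest later ovary differed between the replicates; the SD to ovary of the same day was 0.859 and 0.772. At days 9 and 13 ovary RNA or reads of the same day stay open, because the SD was 0.455 in fat body day 9 replicate 1 and 0.504 in fat body day 13 replicate 2 but 0.761 in fat body day 13 replicate 1. Expression in fat body itself was not tested and stays open.

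For the tissue mean, 3 of 100 drawn splits of the libraries within days, out of 648 possible, called at least as many sequences as the real split, itself counted, which called 119. That share lies under 0.05, the limit set for it. The splits not drawn were not fitted, so the share is an estimate from 100 draws and chance is not taken as excluded. The highest other split called 168 and exchanged fat body day 5 replicate 2 and fat body day 9 replicate 2 with ovary libraries. The library labelled fat body day 9 replicate 2 had a median position of 1.20, on the ovary side. With its label in doubt, splits of the libraries as labelled are no clean measure of chance. Why the highest other split called more than the real split was not tested.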

How the results depend on the processing

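The fits without both day 9 replicate 2 libraries, the edgeR and DESeq2 fits, TMM factors and added isoforms were chosen only after the results were seen; the other alternatives were planned. A pseudocount of 0.5, entries kept apart and a log2 fold change of at least 1 left every count of sequences and lists within 1.5 times its first value. For each change below the cause was not tested, apart from the following. In comparisons that hold no day 9 library, leaving out both day 9 replicate 2 libraries kept the fold changes the same. It altered only the pooled spread and its degrees of freedom.

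With fewer or more sequences tested, the counts moved as follows. A filter of 8 libraries gave 78 for the tissue mean, 90 for tissue at day 13, 0 for ovary day 13 against 9, 35 for fat body across days, 3 for fat body day 13 against 9 and 20 for the interaction. No filter gave 3 and 12 for tissue at days 1 and 5, 17 for ovary day 13 against 9, 9, 4 and 3 for the fat body steps and 12 for the interaction. Without predicted candidates tissue at day 5 gave 15. With isoforms added, ovary day 9 against 5 gave 17, ovary day 13 against 9 gave 0, fat body day 13 against 9 gave 3 and the interaction 20. A pseudocount of 10 gave 1 for ovary day 5 against 1 and 12 for ovary day 13 against 9.

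Scaling moved the counts too. Library totals gave 41 for tissue at day 5, 7 for fat body day 5 against 1, 0 for fat body day 13 against 9 and 4 for the interaction. RLE factors gave 15 for tissue at day 5 and 0 for fat body day 13 against 9. TMM gave 22 for tissue at day 5, 2 for ovary day 5 against 1, 0 for fat body day 5 against 1 and 5 for fat body day 13 against 9. Factors without the 5 most abundant gave 2 and 13 for tissue at days 1 and 5, 2 and 4 for ovary day 5 against 1 and 13 against 9, and 0 for fat body day 5 against 1 and 13 against 9.

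Other tests gave other counts. edgeR on recovered reads gave 0 and 4 for tissue at days 1 and 5, 0 for ovary day 13 against 9, 0, 23 and 26 for the fat body steps and 0 for the interaction. DESeq2 gave 27 and 29 for tissue at days 1 and 5, 7 and 12 for ovary day 5 against 1 and 13 against 9, 115 for fat body across days and 10, 44 and 46 for its steps. A robust limma fit gave 5 for ovary day 13 against 9. A fit of the compared groups alone gave 52 and 33 for tissue at days 1 and 5, 3 and 10 for ovary day 5 against 1 and 13 against 9, 2 for fat body across days, and 0 for fat body day 5 against 1 and 13 against 9; it has no value for the tissue mean and interaction. With an estimated correlation 0 of the 23 camera calls stood.

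With a replicate block, tissue at days 1 and 5 gave 3 and 0, ovary day 13 against 9 gave 1, fat body day 13 against 9 gave 0 and the interaction 1; with the block the tissue mean gave 112, tissue at day 13 gave 130, ovary across days 75, ovary day 9 against 5 gave 25, fat body across days 37 and the list tests 25.

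Without both day 9 replicate 2 libraries the counts were 58, 88 and 111 for tissue at days 1, 5 and 9, 176 for ovary across days, 32, 77 and 5 for its steps, 98 for fat body across days, 32, 2 and 11 for its steps and 97 for the interaction; the tissue mean gave 174, tissue at day 13 gave 177 and the list tests 20.

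Leaving out each library in turn gave 78 to 163 for the tissue mean, 0 to 29, 0 to 60, 0 to 30 and 80 to 174 for tissue at days 1, 5, 9 and 13, 56 to 154 for ovary across days and 0 to 4, 0 to 38 and 0 to 30 for its steps. It gave 4 to 160 for fat body across days, 0 to 12, 0 to 117 and 0 to 101 for its steps, 1 to 108 for the interaction and 18 to 30 for the list tests. The lone library left in a group is assumed to vary like the other groups.

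Of the named sequences, api-miR-87a in fat body across days turned from -3.05 to 1.37 with a pseudocount of 10, 2.61 without fat body day 1 replicate 2 and 3.34 without fat body day 5 replicate 2; with each library left out in turn it ran from -3.65 (without fat body day 1 replicate 1) to 3.34. No other named sequence that passed the test turned under any alternative. Of those that did not pass over the tissue mean, bdo-miR-125 and bdo-miR-124 turned to 0.144 and 0.023 with library totals and bdo-miR-275 to 0.375. The value for bdo-miR-263a_R-3, tissue, mean of 4 days, was -0.016 with RLE factors and with DESeq2. With each library left out in turn, bdo-miR-263a_R-3 ran from -0.125 (without ovary day 9 replicate 1) to 0.314 and bdo-miR-275 from -0.073 (without ovary day 13 replicate 1) to 0.055. The planned fits to deposited counts were not run, because the table holds no counts. Depth limits sequences with few reads, the smallest library having 194098 recovered reads.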

Other observations

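All values in this part were chosen only after the results were seen.

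The seed ATTGCAC, bases 2 to 8 of miR-92, was carried by 5 tested sequences, of which 4 were higher in ovary over the mean of the 4 days. One of the 4 was the candidate PC-3p-204_49387, with the sequence TATTGCACAATCCCCGGCCTGA, at 11587 ± 1040 (SD, n = 2) in ovary day 13 and 84.2 ± 45.8 in fat body day 13. The miR-92a sequence TATTGCACTTGTCCCGGCCTAT stood at 7985 ± 134 and 100 ± 36.3 in the same groups. The remaining member, pte-miR-92b-3p_R+1_1ss10CT, did not pass (log2 0.49, adjusted p = 0.331). The tested predicted candidates together made up between 0.31% and 2.46% of the summed signal of a library.

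Sequences with a miR-2779 name (prefix bmo or mse) were most abundant in fat body day 13, where their summed values were 3024 and 5633, against 48.1 to 1454 in the other 14 libraries. The most abundant, bmo-miR-2779_L-2, averaged 3863 ± 1652 (SD, n = 2) there and 867 in ovary day 13. Of 26 such sequences 15 ended in CCA (57.7%), against 4 of 721 others (0.6%).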
